A study of Homo sapiens with 9 samples.

How the data were processed

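RNA was measured by sequencing in 9 libraries of RT112, an established human bladder carcinoma cell line. The libraries form 3 groups of 3 replicates. Cells of the control group carried a control short hairpin RNA (shNT), and cells of the other groups carried 1 of 2 hairpins against STAG2 (sh1 and sh2). STAG2 encodes a subunit of cohesin, the ring complex that holds sister chromatids together and shapes chromatin loops. Per the labels' protocols, cells were grown with serum, transduced, and then kept without serum, which was meant to limit differences in cell cycle. An equal amount of ERCC spike-in RNA was added to each RNA sample, and stranded poly(A)+ libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. Nothing in the labels says whether the replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be partly technical. Groups and replicate numbers were taken from the sample titles.

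The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, relative to all mapped fragments) with 23370 entries, 92 of them spike-ins, for the 9 libraries. The genome build was hg19, per the submitters' processing notes. The aligner, the quantification program, the gene annotation and any scaling between libraries are not given in the sources used here. Replicates were deposited separately.

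The deposited FPKM values had lost decimal points. No value in the table had exactly 3 decimals, and all 9803 values of 10000 or more were whole, as happens when a spreadsheet reads a point followed by 3 digits as a digit-group mark. Of 10270 values above 0 without a point, 10255 were divided by 1000 and 15 were kept as whole, by which reading lay nearer on the log scale to the median of the gene's values that had kept a point. The divided values were 4.88% of the 210330 values and touched 4613 genes. For 1332 of them no value of the gene had kept a point, and those of 1000 or more were divided. On damage simulated from the restored values, with small random changes, the rule restored 100% of 10284 values and altered 0 undamaged ones. A value that the rule had misread counts as true there, so this cannot show that the real values were restored rightly. On the real values with a reference the smallest margin between the readings was 1.09 on the log10 scale. The 1332 values without a reference have no such check. A further 27 entries had names turned into dates by a spreadsheet, with 2 such names used for more than 1 entry; they stayed in the tests and are not named. All columns of the table belong to the 9 libraries.

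Depth per library is not stated. Spike-in values near the detection limit were read as multiples of the worth of 1 fragment. By this reading 84.2% of 196 low values in 29 spike-ins lay within 0.02 of a whole number of fragments. The lowest value of each spike-in was set to 1 fragment, and library steps were chosen to make most values whole. The share is therefore partly fixed by the fit and does not test the reading. The relative depth from these values differed by 1.17-fold between the deepest and the shallowest library. For most libraries this estimate rests on few spike-ins (3 to 10 that gave the same step), so it is rough, and the absolute depth is unknown. No counting interval is given for that reason, and the spread between replicates is the only error used.

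Differences were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a variance trend on mean expression, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), on genes with a mean FPKM of at least 1 over the 9 libraries. This left 11952 genes. All 9 libraries entered 1 model with the group as its only factor, and the contrasts were sh1 against shNT, sh2 against shNT, the mean of both hairpins against shNT, and sh2 against sh1. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Fold change errors are standard errors, and errors of FPKM are standard deviations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for reading the table, exact permutation tests and sequence searches.

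Gene lists were tested with camera in limma (preset correlation between genes 0.01, Benjamini-Hochberg adjustment over lists), with an estimated correlation and with fry beside it. There were 22 lists: cohesin and its regulators, luminal urothelial markers, basal and squamous markers, mesenchymal markers, epithelial junction genes, mitotic and G2/M genes, S-phase and replication genes, interferon-stimulated genes, NF-kB cytokines and chemokines, p53 targets, ATF4 and unfolded protein response genes, cholesterol synthesis genes, hypoxia and glycolysis genes, MAPK feedback genes, TGF-beta targets, HOX genes, clustered protocadherins, ribosomal proteins, mitochondrially encoded genes, and markers of immune cells, fibroblasts and endothelium. The 18 with at least 5 tested members entered the test. Ribosomal protein genes, keratins and clustered protocadherins have near-identical copies or pseudogenes that can take each other's reads, so single members are uncertain.

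The groups, the tests, the lists, the rule for named genes and a set of alternative settings were fixed before the data were examined. The rule named STAG2 and each tested member of the cohesin list, up to 12 genes each way that passed with both hairpins, up to 4 members of each list each way in the mean contrast or otherwise the member with the smallest adjusted p, and the 6 genes higher and 6 lower with sh2 than with sh1 by fold change with no overlap of the libraries. Those settings were pseudocounts of 0.1 and 0.01, a mean FPKM of at least 5, no filter, and median-of-ratios, quantile and spike-in scaling. Others were the replicate number as a block, only the groups compared, no variance trend, array weights, an absolute log2 fold change of at least 1, and leaving out each library. Chosen after the data were seen were the values as deposited, leaving out genes with a restored value, leaving out shNT replicates 1 and 3, and removing each library's trend on transcript length (lowess, span 0.3).

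Whether replicate numbers pair the samples was read from the data, since the labels do not say what a number shares. Each of the 9 pairs of libraries with the same number in different groups had deviations from the group means that correlated above 0.1 (0.118 to 0.491), against -0.629 to 0.205 with a median of -0.22 for the 18 other pairs between groups, so the numbers were taken to pair the samples. The main model, fixed beforehand, and the exact permutation tests do not use this pairing. For limma and camera, results with the replicate block are given beside the main ones where they differ.

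On simulated data with the real genes and spreads and 200 changed genes, limma called 2.99%, 74.6% and 98.5% of genes changed by a log2 of 0.5, 1 and 2 in the comparison of sh1 with shNT over 11952 genes. For sh2 against shNT these shares were 4.48%, 68.7% and 97.0%, and for the mean of both hairpins 13.4%, 91.0% and 98.5%. Of unchanged genes 2, 5 and 7 were called with sh1, with sh2 and over both. The shares hold for 200 changed genes, and with fewer the adjustment is stricter. They therefore do not tell how many changes were missed in the real data. Of 18 simulated lists camera called the 1 that was shifted by 0.5 and 0 others. The simulated genes varied independently, whereas the correlation estimated between real list members reached 0.91 (ribosomal proteins). The lack of false calls therefore does not carry over to the real lists. Annotated 3' untranslated regions (UTRs), transcript lengths and coordinates came from GENCODE 29 on GRCh38, a different build from that of the deposited table, and were joined by gene symbol. A length was found for 10726 of the tested genes (89.7%).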

Results

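Gene expression was measured as FPKM in 9 libraries of RT112 bladder carcinoma cells, with 3 libraries of the control hairpin (shNT) and 3 of each STAG2 hairpin (sh1 and sh2). The summed FPKM without spike-ins lay between 397792 and 434433 in 8 libraries and was 516464 in shNT replicate 1. Spike-ins made up 1.54% ± 0.101 (SD, n = 3) of the FPKM in control libraries and 1.49% ± 0.241 (SD, n = 6) in silenced libraries, and the difference did not exceed the spread (exact permutation test, two-sided, p = 0.714). In shNT replicate 1 the deviation of genes from their mean level ran opposite to transcript length (Spearman's rho = -0.62 across 10726 genes, which are not independent replicates), against -0.053 to 0.32 in the other 8 libraries.

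The first comparison asked whether the hairpins lowered STAG2, the cohesin subunit they target (X, 123960212 to 124422664, plus strand, GRCh38). STAG2 fell with both hairpins. It stood at 26.4 ± 9.02 FPKM (SD, n = 3) in control libraries, 4.41 ± 0.824 (SD, n = 3) with sh1 and 3.94 ± 0.857 (SD, n = 3) with sh2. The control values were 16.8, 34.7 and 27.7 FPKM, and the highest silenced value was 5.34 FPKM. The log2 fold change was -2.29 (SE 0.25, limma adjusted p = 0.0193) with sh1 and -2.43 (SE 0.25, limma adjusted p = 0.0231) with sh2. Over both it was -2.36 (SE 0.21, limma adjusted p = 0.00797), lower in 6 of 6 silenced libraries. An exact permutation test of the 6 silenced against the 3 control libraries gave a two-sided p of 0.0238, the smallest that free exchange of the libraries allows. That test does not keep the pairing by replicate number. With the replicate block the limma adjusted p over both hairpins was 0.00466. The hairpins differed from each other by less than the spread (log2 difference -0.13, limma adjusted p = 0.851). The limma adjusted p over both hairpins was 0.0556 without shNT replicate 3 and 0.0616 without a filter on low genes, and both single-hairpin calls were lost without a filter, with spike-in scaling (0.0736 and 0.0544) and with only the groups compared (0.138 and 0.196). On leaving out 1 library, the sh2 call held only without shNT replicate 1 or 2 (limma adjusted p from 0.0556 to 0.246 otherwise), and the sh1 call was lost without shNT replicate 2 or 3, sh1 replicate 1 or 2, or sh2 replicate 1 or 3 (0.0564 to 0.187).

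**Figure D1:**
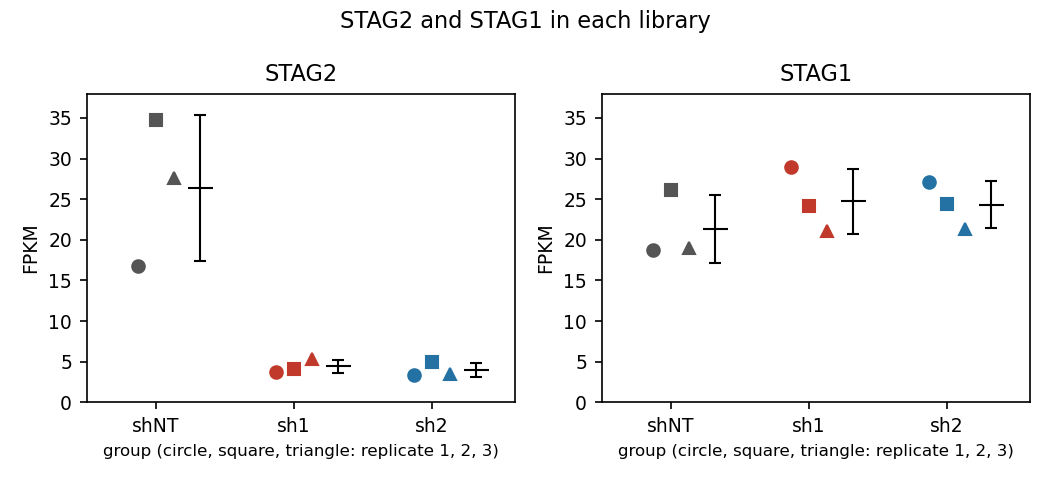
FPKM of STAG2 and of its paralog STAG1 in each of the 9 libraries by group (points, n = 3 per group), with the mean and SD as bars. STAG2 lies at 16.8 or above in the control libraries and at 5.34 or below in the silenced ones, while the STAG1 values of the 3 groups overlap.

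The rest of cohesin and its regulators was examined beside STAG2. Of 20 list members 19 were in the table and 15 were tested. Of these 1 fell (STAG2), 0 rose and 14 did not pass in limma over both hairpins, and the same held adjusted over the list alone. STAG1, which can take the place of STAG2 in the ring, stood at 21.3 ± 4.22 FPKM in control libraries, 24.7 ± 3.95 with sh1 and 24.3 ± 2.88 with sh2 (SD, n = 3 each), a log2 fold change of 0.20 (SE 0.15, limma adjusted p = 0.556). The ring subunits SMC1A and SMC3 had log2 fold changes of 0.20 (SE 0.13) and -0.017 (SE 0.10), and RAD21 had -0.061 (SE 0.14), with limma adjusted p values of 0.499, 0.946 and 0.855. RAD21 had -0.36 with sh1 and 0.23 with sh2, and the difference of 0.59 (SE 0.16) did not pass (limma adjusted p = 0.172). The release factors WAPAL, PDS5A and PDS5B had log2 fold changes of 0.22, 0.20 and 0.086. The loaders NIPBL and MAU2 had 0.30 and -0.13, and the insulator protein CTCF had 0.029. The acetyltransferases ESCO1 and ESCO2 had 0.099 and 0.014, the cohesion protector CDCA5 had -0.29, and the deacetylase HDAC8 had 0.065. The limma adjusted p values of these 10 genes ranged from 0.509 to 0.972. With spike-in scaling, which moves the median of all genes by 0.15 over both hairpins, SMC3, RAD21 and MAU2 had 0.17, 0.13 and 0.038. The list as a set did not pass (camera adjusted p = 0.753), with a median log2 fold change of 0.065, a mean of -0.096 with STAG2 included, and an upward test direction. Its median was -0.0040 without shNT replicate 3.

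Which other genes changed with STAG2 depletion was asked for each hairpin and for both. STAG2 was the 1 gene that passed with both hairpins, and the 1 gene that passed in the mean contrast. With sh1 20 genes passed, 2 higher and 18 lower, and with sh2 STAG2 alone passed. In the mean contrast the smallest limma adjusted p of any other gene was 0.314, and with sh2 it was 0.372. At an unadjusted p under 0.05 there were 1618 genes with sh1, 1513 with sh2 and 1504 over both, where 598 would be expected by chance. On leaving out 1 library the sh2 count went from 450 (without sh2 replicate 1), below that number, to 2665 (without shNT replicate 2). Over both it went from 891 (without sh1 replicate 1) to 2604 (without shNT replicate 2). Array weights gave 709 with sh2 and 662 over both. In 532 genes (273 higher, 259 lower), 4.45% of those tested, all 6 silenced libraries lay beyond all 3 controls, where chance gives 2.38%. With the replicate block the sh1 count was 77 (27 higher, 50 lower), among them the 20 genes. It was 3 without a filter on low genes, 3 with either smaller pseudocount, 0 with spike-in scaling and 0 with only the groups compared in limma (951 and 1255 genes at an unadjusted p under 0.05). It was 0 in limma without shNT replicate 2, shNT replicate 3, sh1 replicate 1, sh2 replicate 1 or sh2 replicate 3 (684 to 2234 genes at an unadjusted p under 0.05), 1 without shNT replicate 1, 2 without sh1 replicate 2 or sh2 replicate 2, and 14 without sh1 replicate 3. Without shNT replicate 2 the counts were 6 with sh2 and 3 over both, HEG1 and PHLDB2 being higher in each; these genes were chosen after their values were seen.

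Of the 20 genes that passed with sh1, the naming rule gave STAG2, TGFB2, CDH1, KCNS3 and VSIG10, the last 3 for their difference between the hairpins, and the others given here were chosen after their values were seen. KCNS3, a modifier subunit of voltage-gated potassium channels, fell by 1.52 on the log2 scale (limma adjusted p = 0.0193), from 18.2 ± 2.13 to 5.69 ± 1.12 FPKM (SD, n = 3 each). CDH1, which encodes E-cadherin, fell by 1.21 from 86.2 ± 14.4 to 36.6 ± 5.02 FPKM (limma adjusted p = 0.0496). The mitochondrial genes VDAC1, an outer membrane channel, and SDHD, a subunit of succinate dehydrogenase, fell by 1.02 and 1.07 (limma adjusted p = 0.0496 for each). BAK1, an effector of apoptosis, fell by 1.04 (limma adjusted p = 0.0496). ACTL6A, ADCK2, CREB3L4, DCAF11, NKAP, POLE3, RCN2, SRPR, TMEM43, TSC22D4 and VSIG10 also fell, by 0.85 to 1.25. TGFB2, a TGF-beta ligand, rose by 1.75 (SE 0.27) from 0.484 ± 0.349 to 4.12 ± 1.92 FPKM (limma adjusted p = 0.0496). ATXN7L3B rose by 1.01 (limma adjusted p = 0.0496). In the sh2 comparison TGFB2 had 1.05 (limma adjusted p = 0.372) and CDH1 had 0.51 (limma adjusted p = 0.372). Of the 16 sh1-lower genes other than STAG2 with a searched 3' UTR, 11 carried the heptamer AGCTTTA, which 15.4% of genes not called between the hairpins carry. Of the 2 higher genes 1 carried it too. Some carriers, such as CDH1 and KCNS3, were also called between the hairpins, so this count is not separate from the one given for that comparison.

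Groups of genes were compared over both hairpins, starting with growth and replication. As a set, ribosomal protein genes fell (camera adjusted p = 4.33e-19, median log2 fold change -0.53), with 54 of 54 tested members lower. Replication genes fell as a set as well (camera adjusted p = 3.22e-04, median -0.18), with 24 of 27 lower. No single member of either list passed in limma, over all genes or adjusted over the list alone. RPL21 had a log2 fold change of -0.89 (SE 0.30, limma adjusted p = 0.342) with 1299, 477 and 601 FPKM in the control libraries. MCM3, a helicase subunit, had -0.44 (SE 0.12, limma adjusted p = 0.326). With an estimated correlation both calls were lost in camera (adjusted p = 0.771 with an estimated correlation), and fry called neither (adjusted p = 0.316). Without shNT replicate 1, the library with the length trend, the ribosomal median was -0.35 (camera adjusted p = 5.79e-11) and the replication median -0.070 (camera adjusted p = 0.0451). The replication list did not pass with that library left out and length trends removed (camera adjusted p = 0.0521), or with genes that had a restored value left out (0.061). With spike-in scaling the replication median turned to 0.012 against 0.15 for all genes, and the ribosomal median was -0.34. Quantile normalization gave ribosomal medians of -0.25 with sh1 and -0.25 with sh2, against -0.50 and -0.56 without it. The ribosomal list mean was 0.72 and 0.45 in shNT replicates 1 and 3 but -0.11 in shNT replicate 2, within the range of the silenced libraries (-0.54 to 0.031).

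Markers of cell state were compared in the same way. Basal and squamous markers rose as a set (camera adjusted p = 3.22e-04, median log2 fold change 0.44), with 19 of 23 tested members higher. Mesenchymal markers rose as a set too (camera adjusted p = 4.46e-04, median 0.76), with 9 of 11 higher. Luminal urothelial markers did not pass (camera adjusted p = 0.261, 18 of 25 lower; 0.0451, median -0.19, without shNT replicate 1), nor did epithelial junction genes (camera adjusted p = 0.753, 12 of 21 lower). The medians of both turned from -0.10 to 0.081 and 0.090 with spike-in scaling. Adjusted over the list alone, 4 mesenchymal members rose and 0 members of the other 3 lists passed in limma. Over all genes none of the members of the 4 lists passed, where 1 gene (STAG2) passed among all 11952 tested. KRT14, a basal keratin, had a log2 fold change of 1.13 (SE 0.43, limma adjusted p = 0.357), with 37.6 ± 17.7 FPKM in control libraries, 47.5 ± 20.4 with sh1 and 147 ± 96.1 with sh2 (SD, n = 3 each). ITGA5, a fibronectin receptor subunit, had 0.72 (SE 0.16, limma adjusted p = 0.314). FGFR3, a luminal receptor, had -0.46 (SE 0.12, limma adjusted p = 0.318), and EPCAM, an epithelial adhesion protein, had -0.52 (SE 0.15, limma adjusted p = 0.328). Both set calls were lost with an estimated correlation (camera adjusted p = 0.771 with an estimated correlation). In shNT replicate 3 the mean of the mesenchymal list lay 1.48 below its average over libraries (-1.48 against 0.080 and -0.26 in the other controls). That of the basal list was -0.66 against -0.10 and -0.27. Without that library the mesenchymal list did not pass (camera adjusted p = 0.113, median 0.23) and the basal list had a median of 0.29 (camera adjusted p = 0.00661), while the luminal and epithelial medians turned to 0.094 and 0.11. With genes that had a restored value left out the basal list did not pass (camera adjusted p = 0.284, median 0.37). That setting takes members such as KRT5 out of the list, since 89.9% of values from 100 to 1000 FPKM were restored ones. A call lost under it can therefore come from the members left out.

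**Figure D2:**
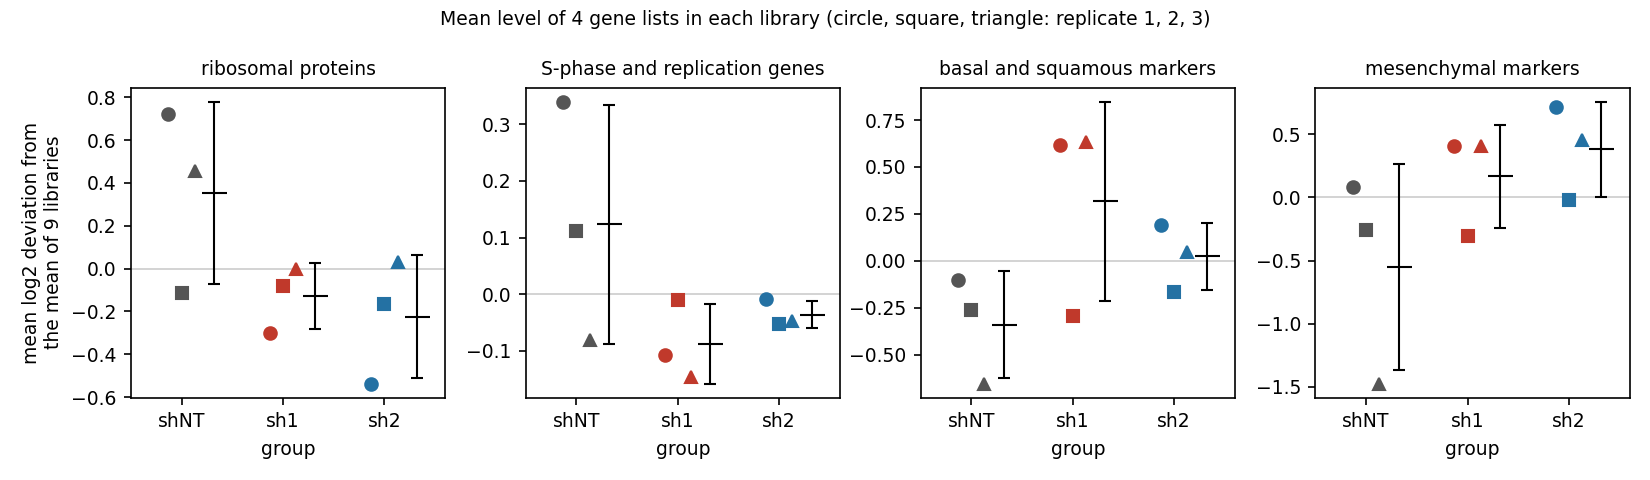
Mean log2 deviation of 4 gene lists from their average over the 9 libraries, per library (points), with the mean and SD of each group as bars (n = 3). The ribosomal list is highest in shNT replicate 1 (0.72), and the mesenchymal list is lowest in shNT replicate 3 (-1.48); with spike-in scaling the median change of the S-phase list turns from -0.18 to 0.012.

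Inflammatory, hypoxia and protocadherin genes were the other lists that passed. NF-kB cytokines and chemokines fell as a set (camera adjusted p = 0.0117, median log2 fold change -0.35, 12 of 14 lower). Hypoxia and glycolysis genes rose (camera adjusted p = 0.0274, median 0.10, 17 of 26 higher), and clustered protocadherins rose (camera adjusted p = 0.0459, median 0.22, 7 of 8 higher). SOD2, a mitochondrial superoxide dismutase induced by NF-kB, had -0.78 (SE 0.18, limma adjusted p = 0.314), with 42.3 ± 15.1 FPKM in control libraries, 17.2 ± 2.14 with sh1 and 31.3 ± 1.05 with sh2 (SD, n = 3 each). KDM3A, a histone demethylase induced by hypoxia, had 0.63 (SE 0.14, limma adjusted p = 0.314), and PCDHB2 had 0.36 (SE 0.15, limma adjusted p = 0.369). Adjusted over the list alone, 1 NF-kB member fell, 1 hypoxia member rose and 0 protocadherins passed in limma. All 3 calls were lost with an estimated correlation (camera adjusted p = 0.771 with an estimated correlation). The mean of the NF-kB list was 1.10 in shNT replicate 3 against -0.16 and -0.20 in the other controls, and without that library the list had a median of 0.12 (camera adjusted p = 0.933). The hypoxia list did not pass without shNT replicate 2 (camera adjusted p = 0.336), shNT replicate 3 (0.312, median -0.0059), sh1 replicate 3 (0.146) or sh2 replicate 3 (0.0598). The protocadherin list did not pass in camera without shNT replicate 3 (0.822), sh1 replicate 2 (0.0933), sh1 replicate 3 (0.0662), sh2 replicate 2 (0.126) or sh2 replicate 3 (0.0598), with array weights (0.162), or with spike-in (0.071), quantile (0.072) or median-of-ratios (0.0517) scaling.

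The remaining lists did not pass over both hairpins, and their medians lay between -0.14 and 0.17. The camera adjusted p was 0.103 for HOX genes, 0.212 for ATF4 and unfolded protein response genes and 0.309 for TGF-beta targets. The HOX list passed with quantile normalization (0.0378), and the ATF4 list passed with the replicate block (0.0446), with spike-in scaling (0.0291) and without sh1 replicate 3 (0.00143, median -0.29). Of the ATF4 list 17 of 22 members were lower, and its median turned from -0.12 to 0.044 with spike-in scaling. The camera adjusted p was 0.691 for interferon-stimulated genes, 0.728 for p53 targets and MAPK feedback genes, and 0.753 for mitotic and G2/M genes and cholesterol synthesis genes. The cholesterol list passed upward without shNT replicate 1 (camera adjusted p = 0.0353, median 0.41) and downward without shNT replicate 3 (2.74e-05, median -0.47). Without shNT replicate 3 the medians of TGF-beta targets and MAPK feedback genes turned from 0.17 to -0.13 and from -0.096 to 0.096. The mitotic median turned from -0.052 to 0.070 without shNT replicate 1 and to 0.024 without sh2 replicate 2, and the interferon median from 0.060 to -0.015 without sh1 replicate 3 and to -0.018 without sh2 replicate 1. Adjusted over the list alone, 3 TGF-beta targets rose and 1 fell in limma, and 0 members of the other lists passed. TGFB2 had a log2 fold change of 1.40 (SE 0.24, limma adjusted p = 0.314). SPRY1, an inhibitor of MAPK signalling, had -0.84 (SE 0.25, limma adjusted p = 0.328), and TRIB3, a stress-induced pseudokinase, had -0.82 (SE 0.31, limma adjusted p = 0.357). SAMD9L had 0.77 (SE 0.21), HOXB8 had -0.64 (SE 0.17), and DDB2, a DNA damage sensor, had -0.51 (SE 0.17). TM7SF2, a sterol reductase, had -0.82 (SE 0.28) and TOP2A, a topoisomerase of dividing cells, had -0.27 (SE 0.12). The limma adjusted p values of these 5 genes ranged from 0.318 to 0.393. Markers of other cell types other than LUM lay at or below 12.1 FPKM in each library. Of 13 immune markers CD68 alone was tested, at -0.41 (SE 0.34, limma adjusted p = 0.581). Of 8 endothelial markers the highest value was 0.665 FPKM (ESAM). Of 10 fibroblast markers 2 were tested, and COL1A1 had at most 6.85 FPKM. LUM, a matrix proteoglycan, had 306 ± 103.2 FPKM in control (SD, n = 3) and 234 ± 92.3 in silenced libraries (SD, n = 6), at -0.44 (SE 0.37, limma adjusted p = 0.595). Of the 13 mitochondrially encoded genes 0 were in the table used here.

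Each hairpin was also compared with the control on its own. With sh1, ribosomal protein genes (camera adjusted p = 9.85e-13, median -0.50), replication genes (6.47e-04, median -0.21) and NF-kB genes (0.0171, median -0.44) fell. Basal (5.51e-04, median 0.49) and mesenchymal markers (0.034, median 0.64, 8 of 11 higher) rose in camera. With sh2, ribosomal protein genes (camera adjusted p = 2.05e-17, median -0.56) and replication genes (0.00759, median -0.22) fell. Mesenchymal markers (camera adjusted p = 1.72e-04, median 1.06, 11 of 11 higher), basal markers (0.0225, median 0.22), TGF-beta targets (0.0389, median 0.36, 15 of 20 higher) and interferon-stimulated genes (0.0431, median 0.16, 18 of 25 higher) rose. None of these calls held in camera with an estimated correlation (adjusted p = 0.913 for sh1 and 0.682 for sh2 with an estimated correlation). The ribosomal list mean was 0.72 and 0.45 in shNT replicates 1 and 3, but -0.11 in shNT replicate 2. It was -0.30, -0.083 and -0.0038 in the sh1 libraries and -0.54, -0.16 and 0.031 in the sh2 libraries. The ribosomal difference thus lay mainly against shNT replicates 1 and 3. Without shNT replicate 3 the sh1 calls of mesenchymal (camera adjusted p = 0.534, median -0.061) and NF-kB genes (0.708, median 0.0075) and the sh2 calls of basal markers (0.0872) and TGF-beta targets (0.351) were lost, while the sh2 call of mesenchymal markers held (0.0127, median 0.53). With genes that had a restored value left out, the sh1 calls of replication (camera adjusted p = 0.129), NF-kB (0.129) and mesenchymal genes (0.287) and the sh2 calls of replication genes (0.144) and basal markers (0.454) were lost. Without shNT replicate 1 both replication calls were lost (camera adjusted p = 0.0751 with sh1 and 0.127 with sh2), and the sh2 call was lost with spike-in scaling (0.0792, median 0.031). The sh1 mesenchymal call was also lost in camera without sh1 replicate 3 (0.197) or sh2 replicate 3 (0.0615), without a filter (0.0785, median 0.054) and with the length trend removed (0.0651), and the sh1 NF-kB call without sh1 replicate 2 (0.0741). The sh2 basal call was lost in camera with spike-in scaling (0.0792) and, like that of TGF-beta targets, without a filter (0.0642 for each). With genes that had a restored value left out the basal list was lower with sh2 (median -0.19) and lower with sh2 than with sh1 (camera adjusted p = 0.00145, median -0.74). The sh2 interferon call was lost in camera without shNT replicate 2 (0.175) or sh2 replicate 1 (0.287), without a filter (0.0695), at a mean FPKM of at least 5 (0.22), and with quantile (0.0634) or spike-in scaling (0.0712). Further lists passed under several of the settings; with the replicate block, for example, camera also called mitotic (adjusted p = 0.0436), ATF4 (0.0294) and hypoxia genes (0.0436) with sh1, and NF-kB genes (0.0169) and protocadherins (0.0375) with sh2.

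How far the hairpins differed from each other was tested directly. Between sh2 and sh1 26 genes differed in limma, 17 higher and 9 lower with sh2. CDH1 was higher with sh2 by 1.72 (SE 0.17, limma adjusted p = 0.0197), with 86.2 ± 14.4 FPKM in control libraries, 36.6 ± 5.02 with sh1 and 123 ± 17.5 with sh2 (SD, n = 3 each). KCNS3 was higher by 1.35 (SE 0.15, limma adjusted p = 0.0233). VSIG10, ARPP19, TGOLN2 and EIF2AK3, a kinase of the unfolded protein response, were higher by 1.34, 1.34, 1.33 and 1.21 (limma adjusted p = 0.0451 for each). ALDH1A1, a retinaldehyde dehydrogenase, was lower with sh2, at a log2 difference of -1.78 (SE 0.28, limma adjusted p = 0.0451), with 55.1 ± 9.44 FPKM in control libraries, 118 ± 30.5 with sh1 and 34.4 ± 13.5 with sh2 (SD, n = 3 each). C10orf26, HDHD1, RAB1A, PANX2 and INPP5A were lower by log2 differences of -1.72, -1.72, -1.31, -1.30 and -1.03 (limma adjusted p = 0.0451 for each). Mitotic and G2/M genes were higher with sh2 as a set (camera adjusted p = 0.00225, median 0.25, 20 of 26 higher), as were interferon-stimulated genes (camera adjusted p = 0.0156, median 0.11, 18 of 25 higher), with medians above 0 in each scaling. Without sh2 replicate 1 neither passed (camera adjusted p = 0.374 for each, medians 0.13 and 0.0037), nor did the interferon list without sh1 replicate 3 (0.0863). With genes that had a restored value left out they did not pass either (camera adjusted p = 0.106 and 0.111). Neither held in camera with an estimated correlation (adjusted p = 0.944 with an estimated correlation). Adjusted over the list alone, 3 interferon-stimulated genes rose and 0 mitotic genes passed in limma. Of the epithelial junction genes 1 rose (CDH1), while 18 of 21 had lower values with sh2. With the replicate block 17 genes passed (12 higher, 5 lower; 12 shared with the 26). Spike-in scaling, which shifts the median of all genes by 0.12 here, gave 2 and no filter gave 0 in limma (2376 at an unadjusted p under 0.05), while only the groups compared gave 92 (61 higher, 31 lower) and array weights 458 (250 higher, 208 lower). The count was 0 in limma without sh1 replicate 1, sh2 replicate 1 or sh2 replicate 3 (901 to 1303 at an unadjusted p under 0.05), 2 without sh1 replicate 2, 6 without shNT replicate 2, 14 without sh2 replicate 2, 34 without shNT replicate 1, and 52 without shNT replicate 3.

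**Figure D3:**
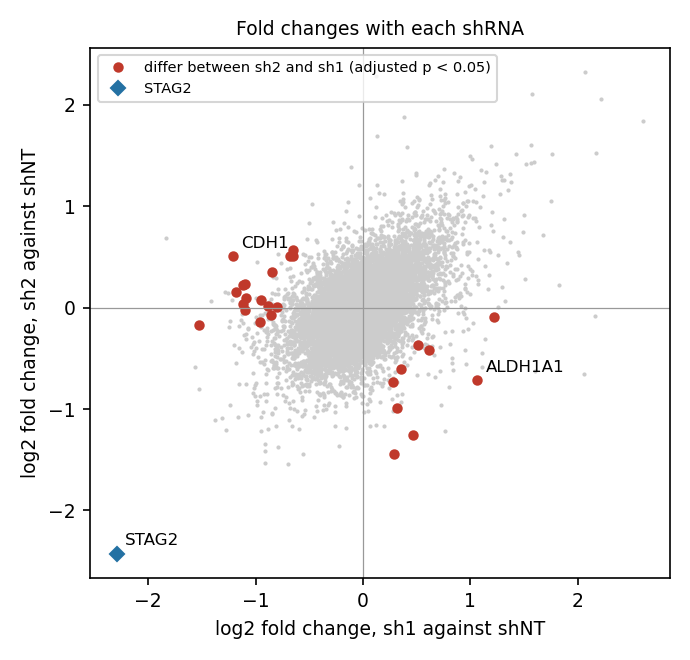
Log2 fold change against shNT with sh1 (x axis) and with sh2 (y axis) for the 11952 tested genes, on the log2(FPKM + 1) scale. Red points are the 26 genes that differ between the hairpins, among them CDH1 (-1.21 with sh1, 0.51 with sh2) and ALDH1A1, and the blue diamond is STAG2 (-2.29 and -2.43).

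The similarity of the hairpins' effects was set against what shared controls give. Across genes, which are not independent replicates, the log2 fold changes of sh1 and sh2 correlated at 0.532. In 100 simulations of unchanged groups that shared 3 controls, redrawn each time with the spread of the control libraries, it was 0.677 on average (at most 0.699). The covariance was 0.0573 against 0.0508 simulated (at most 0.0553). The simulation draws genes independently of each other, so the simulated ranges may be too narrow. It also leaves out effects shared by libraries of equal number, which can raise or lower the covariance. In sign, 67.8% of genes went the same way against 69.0% simulated (at most 70.0%). STAG2 was called with both hairpins where the simulations gave 0.03 genes on average (at most 1) and independent lists would share 0.00151 lower genes. With 3 control libraries the controls could not be split into parts of at least 2 libraries. In correlation and sign, the simulated shared controls gave on average at least as much likeness as was observed. The covariance alone lay above its simulated values, within the limits given above. These measures therefore do not set an effect of both hairpins apart from the shared controls.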

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

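The division of the 6 libraries into other groups, the shift per library of genes with the heptamer, the search of a neighbouring heptamer, the limit set on the sh2 share and the alternative that removes a length trend were tests chosen after the result was seen. The count of calls without carriers of the heptamer was also chosen then and is not a test. The hairpins target the same gene, and a test of the difference between them brought up 26 genes in limma. CDH1, KCNS3, VSIG10, ARPP19, TGOLN2 and EIF2AK3 were higher with sh2 than with sh1 by a log2 of 1.72, 1.35, 1.34, 1.34, 1.33 and 1.21. ALDH1A1, C10orf26, HDHD1, RAB1A, PANX2 and INPP5A were lower with sh2, at log2 differences of -1.78, -1.72, -1.72, -1.31, -1.30 and -1.03. Mitotic and G2/M genes (camera adjusted p = 0.00225) and interferon-stimulated genes (camera adjusted p = 0.0156) were higher with sh2 as sets, with adjusted p = 0.944 with an estimated correlation. The mean of the mitotic list was 0.36, -0.20 and 0.15 in the sh2 libraries and -0.19, -0.14 and -0.076 in the sh1 libraries, so that 1 sh2 library lay below all sh1 libraries. Without sh2 replicate 1 neither list passed (camera adjusted p = 0.374 for each).

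Genes lower with one hairpin than with the other were searched for common 3' UTR sequences, with the called genes set aside. Log2 differences were capped at 2 either way and adjusted for 3' UTR length, its share of A and T, and mean expression. Shifts are means of the adjusted values, and z is the shift over its standard error across genes. The shifts per library were adjusted in the same way. Of 16304 heptamers AGCTTTA had the largest z between the hairpins (10.0, against at most 4.43 in 100 shuffles). This heptamer had 1583 genes, lower with sh1 by an adjusted mean of 0.084. In STAG2 it occurs in the window GTCTGAGTTGCTCAGCTTTAT (GRCh38, X, 124071256 to 124071276, exon 25 of 34, coding sequence) and in the 3' UTR (X, 124101797 to 124101803, exon 34). Its genes lay lower in the 3 sh1 libraries (-0.088, -0.061 and -0.044) than in the 6 others (0.024 to 0.045), which follows in part from the choice of the heptamer by its difference between the hairpins. For sh2 the heptamer TTACCGA ranked first by z (-5.36, against 4.42 in shuffles), its 165 genes being lower with sh2 by an adjusted mean of 0.13. It occurs in STAG2 (GRCh38, X, 124086622 to 124086628, exon 30, coding sequence). The overlapping heptamer CTTACCG came close behind (z = -5.30), its 160 genes also being lower by 0.13. The adjusted shift of the 165 genes with TTACCGA, against genes without it, was -0.17, -0.040 and -0.070 in the sh2 libraries. Of the genes called in the main fit, 6 with sh1 and 9 between the hairpins were neither carriers of AGCTTTA nor unsearched. STAG2, itself a carrier, is not among the 6, and nothing was refitted for this count.

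A candidate explanation for the genes lower with sh1 is that sh1 also lowers transcripts whose 3' UTRs pair with its seed: AGCTTTA was carried by 14 of the 16 called genes searched (87.5%, against 15.4% of 10253 uncalled genes, one-sided Fisher's exact p = 4.06e-10), although VSIG10 and TGOLN2 lack it and the sequence of sh1 is not given in the sources used here. A trend on transcript length is argued against as the whole source of the difference, since 25 of the 26 genes passed with each library's trend removed. Of the genes lower with sh2, 0 of the 7 searched carried TTACCGA, which meets the bound set beforehand against a seed effect, but 0 of 7 allows a share of up to 41.0% (exact binomial, 95%) against 1.61% of uncalled genes. The overlapping heptamer CTTACCG, close behind in z (-5.30 against -5.36), was carried by 2 of the 7 (28.6% against 1.56%, one-sided Fisher's exact p = 0.00494). The bound thus rests on the narrow lead of TTACCGA. A seed effect of sh2 stays open for a few genes, while most of the 7 are not accounted for and C10orf26 and HDHD1 were not searched. Effects of STAG2 depletion that differ between the hairpins also stay open and were not tested, with STAG2 itself differing by -0.13 (limma adjusted p = 0.851).

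Whether another division of the libraries gives as many genes was counted for the comparison of the hairpins. The 6 sh1 and sh2 libraries make 10 splits, too few for a share under 0.05; the real split gave 26 genes and the highest other 0, so that 1 of 10 gave as many. Of the 4 splits that part the 3 pairs of equal number, the real one gave 17 genes with the replicate block and the highest other 0.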

How the results depend on the processing

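The values as deposited, leaving out restored genes or shNT replicates 1 and 3, and removing the length trend were tests chosen after the data were seen. The count of calls without genes that carry AGCTTTA or have no searched 3' UTR was also chosen then and is not a test. For each change the cause was not tested unless stated. The groups hold 3 libraries each, the spread is shared over 9, and depth is unknown.

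STAG2 kept its direction in each setting (limma adjusted p from 5.66e-04 to 0.0616); its log2 fold change was -2.36 without a filter (adjusted p = 0.0616, with 19462 genes tested) and -2.64 to -2.14 on leaving out each library. Of sh1 genes, pseudocounts of 0.1 and 0.01 gave 3 and 3. No filter gave 3 with sh1 (1 higher, 2 lower), 0 with sh2 (limma, 1940 at an unadjusted p under 0.05), 0 between hairpins (2376), 0 with both, and over both hairpins 1 gene that was not STAG2 (LOC100130348, -0.13). Spike-in scaling gave 0 with sh1 (limma, 951 at an unadjusted p under 0.05), 0 with sh2 (1576), 2 between hairpins (2 higher, 0 lower) and 0 with both. Only the groups compared gave 0 with sh1 (1255), 0 with sh2 (981), 92 between hairpins (61 higher, 31 lower) and 0 with both. Array weights gave 458 between hairpins (250 higher, 208 lower). The replicate block gave 77 genes with sh1 and 17 between hairpins, and beyond these and the lists given with it changed no other call. With an estimated correlation 0 lists passed in camera, and with fry 0; other planned settings with 9 libraries gave 6 to 8 lists.

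As deposited, with 1000-fold errors left in, there were 10 genes with sh1 (4 higher, 6 lower), 6 with sh2, 4 over both, 10 between hairpins (4 higher, 6 lower), 3 with both and 2 lists; C10orf26 and PANX2 turned to 1.49 and 1.99 between hairpins, and BAK1 and SDHD to 2.25 and 2.23 with sh1, because of those errors. Without genes that had a restored value (7395 genes left) sh1 gave 3 genes, and 4 lists passed, without the basal (camera adjusted p = 0.284) and replication lists (0.061), the ribosomal list having too few genes left to be tested. Of values from 100 to 1000 FPKM 89.9% were restored ones, so this setting takes out many highly expressed genes. Calls lost under it do not tell the repair from the loss of members. Without shNT replicates 1 and 3, the lone control being assumed to vary like the other groups, sh1 gave 1 and the hairpins 92. With the length trend removed sh1 gave 37 (5 higher, 32 lower) and the hairpins 51 (36 higher, 15 lower); with the replicate block as well 155 and 184; with the trend removed and no shNT replicate 1, sh1 gave 2. Of the calls of the main fit, 6 with sh1 and 9 between the hairpins were neither AGCTTTA genes nor genes with no searched 3' UTR. STAG2 was left out there as a carrier. No fit or adjustment was redone, so these counts follow from the carriers among the calls.

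Leaving out each library gave 0 to 14 genes with sh1 (14 without sh1 replicate 3), 0 to 6 with sh2 (6 without shNT replicate 2, HEG1 and PHLDB2 among them), 0 to 3 over both, 0 to 52 between hairpins (52 without shNT replicate 3), 0 to 1 with both and 4 to 9 lists. Genes near 0 crossed it: CD68 -0.69 to 0.0075, CTCF -0.079 to 0.12, ESCO1 -0.0081 to 0.20, ESCO2 -0.12 to 0.15, HDAC8 -0.0040 to 0.12, NIPBL -0.0082 to 0.49 and SMC3 -0.059 to 0.024. Quantile scaling turned RAD21 to 0.015 and ESCO2 to -0.0039, spike-in scaling SMC3, RAD21 and MAU2 to 0.17, 0.13 and 0.038, and array weights PDS5B, ESCO1 and ESCO2 to -0.0054, -0.0069 and -0.072. Of other values of single genes, 338 stayed on their side of the threshold and 244 no longer passed on leaving out a library, and 686 and 205 under other settings.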

Other observations

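Tests of the basal and mesenchymal patterns, the spread allowed around the ribosomal values, the splits of the sh1 and sh2 comparisons and the simulation of shared controls were chosen, or changed, after the result was seen. Cholesterol synthesis genes were lowest in the replicates numbered 3. The mean of this list was -1.07, -0.47 and -0.31 in the replicates numbered 3 of shNT, sh1 and sh2, below the 6 other libraries (-0.0013 to 0.56). Over both hairpins the list did not pass (camera adjusted p = 0.753), but it passed upward without shNT replicate 1 (0.0353, median 0.41) and downward without shNT replicate 3 (2.74e-05, median -0.47). No test of the replicate number was run on this list, and it was noticed after the values were seen. The list holds enzymes of sterol synthesis and the LDL receptor, which cells regulate by sterol supply.

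Ribosomal protein genes were lower in the silenced libraries, and the highest list mean was that of shNT replicate 1 (0.72), the library with the length trend. Without that library and with each library's length trend removed the list still passed with a median of -0.35, which meets the bound set beforehand against that trend as the source, but at the level of libraries the difference was then -0.33 (SE 0.18), within 2 SE of 0, so the trend is not excluded. STAG2 depletion would lower the list in each silenced library. In that direction went 15 of the 18 pairs of a silenced and a control library. However, shNT replicate 2 (-0.11) lay at or below 3 silenced libraries, which meets the bound set against it, though none by more than the SD within groups of 0.31. These pairs share libraries and cross replicate numbers, and the SD and SE leave out the pairing. By number, the means of shNT, sh1 and sh2 were 0.72, -0.30 and -0.54 for 1, -0.11, -0.083 and -0.16 for 2, and 0.45, -0.0038 and 0.031 for 3. The length trend and STAG2 depletion therefore both stay open and cannot be told apart with 3 controls. Near-identical pseudogenes were not tested as a source.

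Basal and mesenchymal genes were higher in the silenced libraries, and shNT replicate 3 was the lowest library for both lists. For the mesenchymal list that 1 control remains a candidate explanation of a part. Without it the call over both hairpins ended (camera adjusted p = 0.113) while that of sh2 held (0.0127, median 0.53). The difference between libraries went from 0.83 (SE 0.38) to 0.37 (SE 0.29). Leaving out a control chosen because it was lowest shrinks the difference whatever its cause, so the shrinkage decides for no source. The basal list still passed (camera adjusted p = 0.00661), yet its difference went from 0.51 (SE 0.26) to 0.35 (SE 0.29), within the spread, so that control is not excluded as its source. STAG2 depletion stays open for both, with 15 of 18 pairs in its direction for the basal list and 15 of 18 for the mesenchymal list, and with 2 silenced libraries at or below the highest control in each, by less than 1 SD (0.36 and 0.57). These pairs also cross replicate numbers, and the SDs and SEs leave out the pairing. STAG2 stood at 27.7 FPKM in shNT replicate 3, within the range of the controls.

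Other divisions of the libraries were counted for the comparisons with the control. For the mean of both hairpins chance cannot be excluded for genes: 8 of the 84 splits gave at least the real count of 1, up to 31, the highest being the split that sets the 3 sh1 libraries apart, which points to a structure of the samples other than the control against the rest. The split that sets the 3 replicates numbered 3 apart gave 12, and with the replicate block the real split gave 1 gene against up to 61 in the 27 splits that part the numbers evenly. For lists chance cannot be excluded either, since 49 of the 84 splits gave at least the real 7, up to 11 with shNT replicate 3, sh1 replicate 1 and sh2 replicate 1 apart, and the 3 replicates numbered 2 gave 10; with the replicate block the real split, fitted as 2 groups like the others, gave 9 lists (8 with the hairpins fitted apart) and the highest of the 27 gave 11. For genes called with both hairpins, 6 of 100 drawn assignments gave at least the real 1, at most 1, so chance cannot be excluded for the count, which says nothing about that gene being the targeted one. The 10 splits of 6 libraries are too few for a share under 0.05: with sh1 the real split gave 20 genes and the highest other 0 (1 of 10 as many), and with sh2 the real split gave 1 and the highest other 1 (2 of 10 as many). Of the 4 splits that part the pairs, the real ones gave 77 and 1 genes with the block and the highest others 0 and 0.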
